A study of Mus musculus with 8 samples.

How the data were processed

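Leukocytes of mouse hepatocellular carcinoma and of non-tumor liver, sorted into NK1.1+ and NK1.1- fractions from animals labelled HET or KO, were profiled by 3' single-cell RNA sequencing (Chromium Next GEM Single Cell 3' v3.1, per the labels). The 8 libraries form 8 groups of 1 library, by tissue, sort and genotype. The labels do not name the targeted gene or the deleted part, and the number of animals per library is not stated in them. Per the file headers, the authors made the deposited matrices with Cell Ranger 6.0.1, against mm10 per the submitters' notes, and the values are raw UMI counts per gene and cell barcode. Values were checked to be whole numbers of at least 1 in sparse matrices. Each library's own matrix was used, with 31053 genes. The authors also deposited aggregated matrices of counts, in which, from the values, the deeper libraries were reduced in depth.

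The 45355 barcodes were reduced to cells with at least 250 genes and at most 10% mitochondrial UMIs, which removed 1443. Scrublet doublet scores (with scikit-image 0.26.0) were computed per library in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 cells, 1980 in all, leaving 41932 cells. Counts were scaled to 10000 per cell and logged, 2000 highly variable genes were chosen across libraries, and 1891 of them were used after mitochondrial, ribosomal, receptor segment, sex, hepatocyte and hemoglobin genes were left out. A graph of 20 nearest neighbors on 30 principal components was clustered by Leiden (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0, with seed 1, into 36 clusters. No batch correction was made, since library and group are the same thing here.

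A cluster was named for the marker list with the highest mean log2 fold over the other cells (20 CPM added), where that mean was at least 1.0, a bound set after the clusters were seen. In all 26 clusters were named and 10, with 8635 cells, were not. Names carry the ending -like because they rest on transcripts alone. Several classes join clusters: CD8 T-like, monocyte-like, neutrophil-like, macrophage-like and plasmacytoid dendritic-like cells each came mostly from different clusters in different libraries, whereas NK-like, ILC1-like and innate-like T-like cells were 1 cluster each.

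Shares of cells were given exact Clopper-Pearson 95% intervals. Levels were UMIs summed over the cells of a class in a library, scaled by the total UMIs of that sum to the usual CPM unit, with exact Poisson intervals, and ratios of 2 sums were given exact conditional binomial intervals. A class was compared where each library held at least 100 cells. With 1 library per group no test across animals was made, no p-value was computed, and all intervals cover counting error only; the limit that a count of 0 allows was set at 3 counts. Genes were described by size: eligible with at least 100 UMIs in the 2 sums together and at least 20 CPM in the higher, and past the rule at a ratio of 2.0 or more after 0.5 was added to each count. The rule and the intervals were tested on simulated data drawn from the HET sums by Poisson counts: of genes set to a fold of 2.5, 100.0% passed in the tumor NK-like comparison and 97.0% in the nontumor comparison, 5 of 5010 unchanged genes passed in the latter, and intervals held the set fold for 92.4% to 97.0% of genes. The changed genes were drawn from those expected at 2 times the UMI and CPM minimums or more, so changed genes near the minimums were not tried. Poisson counts also leave out UMIs that clump in single cells.

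The groups, comparisons, the size rule, 25 gene lists and the marker lists were fixed before the data were examined. The lists covered cytotoxic effectors, NK activating receptors, inhibitory receptors, early and late NK maturation, tissue residency, interferon-induced genes, the IL-27 receptor and pathway, cytokines and chemokines, activation and metabolism, cell cycle, dissociation stress, class II, tumor-associated macrophage, Kupffer, inflammatory myeloid, regulatory T, naive and memory T, hepatocyte, erythrocyte, liver endothelium, RNA of neutrophils, of B and plasma cells and of myeloid cells, and sex. For each list the median log2 ratio was taken over its members with at least 100 UMIs in the 2 sums, with no CPM minimum. The median was given an interval from 1000 Poisson draws. It was also given its percentile among 10000 random lists under the same UMI minimum, matched on mean expression in 20 bins. The percentile describes 2 libraries and is not a test. Some lists share members, and the class II, inflammatory and macrophage lists hold genes that free RNA brings into lymphocytes.

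Named genes were chosen by a rule fixed in advance. Mitochondrial, ribosomal, receptor segment, clone-named, hepatocyte, erythrocyte and sex genes were left out. Of those past the size rule, up to 10 with the highest and 10 with the lowest ratio were named for NK-like cells, up to 5 each for ILC1-like cells, and up to 3 each for other classes of at least 200 cells in both libraries, plus up to 5 each way in both tissues and the extremes of each list. Il27ra, Ifng, Gzmb, Gzma, Prf1, Klrg1, Klrk1, Ncr1, Pdcd1, Lag3, Tigit, Havcr2 and Ctla4 were looked up in every class. The rule also covered tumor against nontumor in KO animals, for which counts alone are given because the libraries differ in depth. Some genes that the rule selects are not reported here. Other names are stated as chosen after their values were seen. Genes that set the NK-like cluster apart are given with their value in a clustering without them.

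Free RNA was estimated for each lymphocyte class of a library by taking all of its neutrophil transcripts as free RNA with the profile summed over all cells of that library, so it is an upper estimate where neutrophil cells were misplaced in a class, and neutrophil genes are covered by construction. Coordinates are from GENCODE vM21 on GRCm38. Alternatives planned were no doublet removal, a filter of 500 genes and 5% mitochondrial UMIs, Leiden at 0.5 and 2.0, a class for each cell by its own markers (score at least 0.25), the aggregated matrices, edgeR 4.0.16 TMM and median-of-ratios factors, the mean of each cell's CPM, cells thinned to 1500 UMIs, other UMI minimums, ratios of 1.5 and 3, and all cells for Il27ra. Added after the data were seen were a clustering without 109 leading and list genes, cells of at least 2000 UMIs, shares among NK-like, ILC1-like and innate-like T-like cells, classes without their cluster of fewest UMIs, cells with no Cd3 UMI, free RNA subtracted, thinned cells for list medians, and settings other than TMM and median-of-ratios factors for differences between tissues. The aggregated matrix of all 8 libraries was not used for levels. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.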

Results

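The series profiled leukocytes (CD45+ cells) sorted from mouse hepatocellular carcinoma and from non-tumor liver by droplet sequencing of the 3' ends of transcripts. Each tissue was split by the surface receptor NK1.1, which NK cells, type 1 innate lymphoid cells (ILC1) and some T cells carry. Animals were labelled HET or KO, and the series title places IL-27 signaling in innate cytotoxic cells at the center of the study, so the comparison of KO with HET asks what differs in these cells when the pathway is disrupted. There was 1 library in each of the 8 groups, so no test across animals was made; every interval is a 95% interval for counting error only, and every difference is a difference between 2 libraries.

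The tumor NK1.1+ libraries held 33241718 UMIs (HET, 5078 barcodes, median 5206.5 per barcode) and 41961730 UMIs (KO, 5588 barcodes, median 5608.0). The tumor NK1.1- libraries held 33570619 UMIs (HET, 5919 barcodes, median 4375.0) and 35624192 UMIs (KO, 4972 barcodes, median 5392.0). The nontumor HET libraries held 31529347 UMIs (NK1.1+, 5713 barcodes, median 4861.0) and 30231351 UMIs (NK1.1-, 4012 barcodes, median 5643.5). The nontumor KO libraries were far shallower, with 17176118 UMIs over 7383 NK1.1+ barcodes (median 1283.0) and 14392026 UMIs over 6690 NK1.1- barcodes (median 1066.0). After filtering, 41932 cells fell into 36 clusters, of which 26 received a class name from their marker genes.

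Il27ra, which encodes the ligand-specific chain of the IL-27 receptor (ENSMUSG00000005465, chromosome 8, 84030294 to 84042589, GRCm38), was detected in every library. In the tumor NK1.1+ sort it stood at 35.4 CPM (33.4 to 37.6; the UMIs of a gene scaled to a fixed total) in the HET library and 12.2 CPM (11.1 to 13.4) in the KO library, over all cells. In the nontumor NK1.1+ sort it stood at 42.7 CPM (40.4 to 45.2) in the HET library and 31.5 CPM (28.8 to 34.4) in the KO library. In the NK1.1- sort the values were 29.4 CPM (HET) and 11.9 CPM (KO) in tumor, and 19.8 CPM (HET) and 9.95 CPM (KO) in nontumor tissue. Within NK-like cells of tumor the log2 ratio of KO to HET was -0.89 (-1.32 to -0.50), and in nontumor tissue it was 0.21 (-0.33 to 0.70), with no settled size or direction, since it was 0.98 among cells with no Cd3 UMI, 0.70 in the aggregated matrix and -0.20 in cells thinned to equal depth. ILC1-like cells gave -0.91 (-1.39 to -0.47) in tumor and -0.49 (-1.03 to -0.01) in nontumor tissue. B-like cells of the tumor NK1.1- sort gave -0.62 (-1.04 to -0.21). The labels do not state which part of the gene was deleted and 3' reads cover the transcript end alone, so RNA left in the KO libraries does not speak against their label. Over all cells the level was lower in the KO library in each of the 4 pairs of tissue and sort. The level over all cells also follows the mix of classes.

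Transcripts close to Il27ra on chromosome 8 also differed between the KO and HET libraries. Mri1, a methionine salvage enzyme (ENSMUSG00000004996, 84249906 to 84257326), was lower in KO in 11 of the 11 class comparisons where it had enough UMIs, with a median log2 ratio of -0.94. Gm42031, a long noncoding RNA (ENSMUSG00000110386, 85125872 to 85132289), was lower in 14 of 14, with a median of -1.46. Classes of the same library share its animals, so these comparisons are not independent repeats. Of 58 other genes within 5 Mb, 0 had ratios of 1 sign and at least 1.5 times in all of their comparisons, a rule that Mri1 does not meet either, and 2 had ratios of 1 sign. Between Mri1 and Gm42031, Gadd45gip1 (median -0.68) and Trmt1 (-0.38) were each lower in KO in 12 of 13 comparisons, while Asna1 (0.28) was higher in 15 of 17. Gm42031, Gadd45gip1, Trmt1, Asna1 and the position of these genes were singled out after the values were seen.

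**Figure D1:**
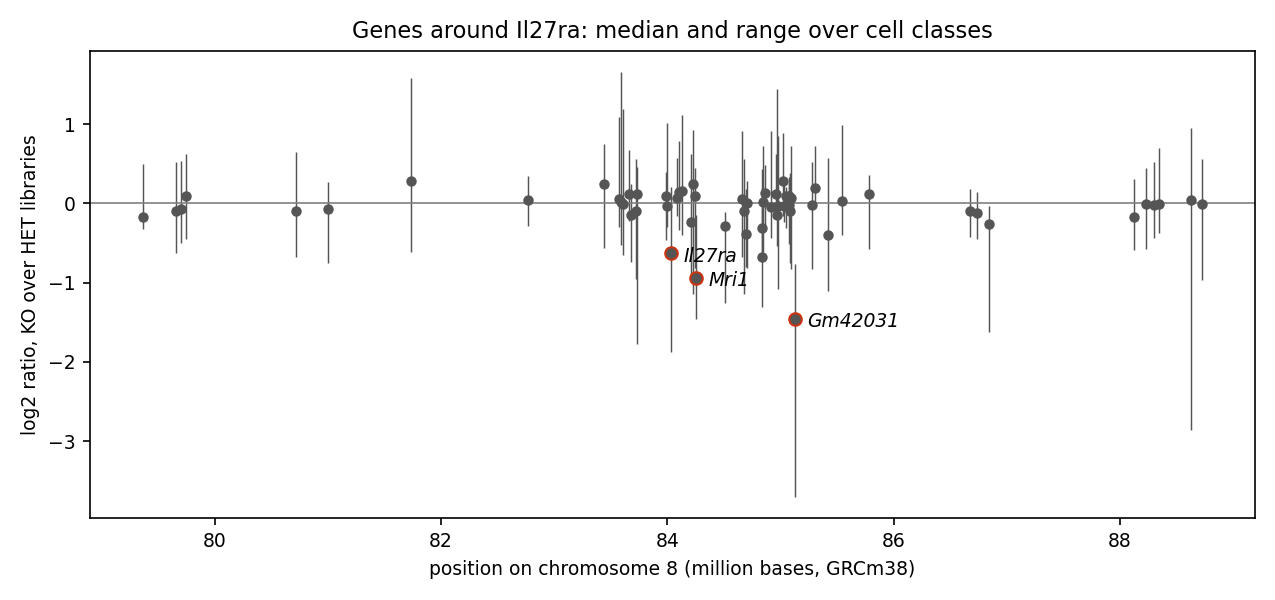
Median log2 ratio of KO over HET over the class comparisons of each gene (points, y axis; bars are the lowest and highest ratio) against position on chromosome 8 around Il27ra (x axis, Mb, GRCm38). Gm42031 lies at -1.46, Mri1 at -0.94 and Il27ra at -0.63.

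Innate cytotoxic lymphocytes made up a smaller share of the tumor NK1.1+ sort in the KO library, and neutrophil-like and monocyte-like cells a larger one. NK-like cells were 41.9% (40.5 to 43.3; exact Clopper-Pearson intervals throughout) of 4802 HET cells and 16.2% (15.2 to 17.2) of 5168 KO cells, a share 2.59 times lower in the KO library (log2 ratio -1.37, -1.49 to -1.26). ILC1-like cells were 10.0% (9.18 to 10.9) of HET cells and 6.31% (5.66 to 7.01) of KO cells, 1.59 times lower. Neutrophil-like cells were 1.92% (1.55 to 2.35) of HET cells and 21.0% (19.9 to 22.2) of KO cells, 10.9 times higher. Monocyte-like cells were 0.875% (0.631 to 1.18) of HET cells and 14.2% (13.2 to 15.2) of KO cells, 16.0 times higher. CD8 T-like cells were 4.75 times higher in the KO library, at 6.77% (6.10 to 7.49), mostly by a cluster with Klra7 and Gzmb among its leading genes, which held 264 KO and 21 HET cells, and innate-like T-like cells differed little, at 3.42% (2.92 to 3.97) in HET and 4.22% (3.69 to 4.80) in KO. In the tumor NK1.1- sort NK-like cells were 1 of 5562 HET and 0 of 4637 KO cells (limit 0.0647%), so they were nearly absent from both libraries.

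The purity of each sort was not measured apart from these shares. Neutrophil-like and monocyte-like cells are not among the cells named above as carriers of NK1.1. In tumor the log2 ratio of the neutrophil-like share was 3.45 in the NK1.1+ sort and 1.68 in the NK1.1- sort. How far the shares of the NK1.1+ sort, that of NK-like cells included, reflect the tissue or the sort was not tested. Klrb1c, which encodes NK1.1 and falls with the share of NK-like cells, stood at 317 CPM in the tumor HET library and 106 CPM in the tumor KO library, and at 371 and 233 CPM in the nontumor HET and KO libraries. Counted among NK-like, ILC1-like and innate-like T-like cells alone, the log2 ratio of the NK-like share was -0.32 in tumor and -0.26 in nontumor tissue, and that of the ILC1-like share was 0.38 in tumor, the opposite direction, and -0.18 in nontumor tissue.

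In nontumor tissue the same classes were lower in the KO library. NK-like cells were 24.8% (23.7 to 26.0) of 5334 HET cells and 5.99% (5.43 to 6.59) of 6577 KO cells, 4.14 times lower. ILC1-like cells were 14.4% (13.4 to 15.3) of HET cells and 3.68% (3.24 to 4.16) of KO cells, 3.90 times lower. Innate-like T-like cells were 31.7% (30.5 to 33.0) of HET cells and 10.9% (10.1 to 11.7) of KO cells, 2.91 times lower. KO cells of this class had a median of 3841 UMIs, against 1305 over their library. The class held 716 KO and 1693 HET cells of any depth, against 2404 and 5145 cells of 2000 UMIs or more in these libraries. So the 2.91 times may come mostly from KO cells of few UMIs. The size among deeper cells is not settled. Among cells of 2000 UMIs or more, which were 96.5% of the cells of this HET library and 36.6% of those of this KO library, the log2 ratio was -1.18 for NK-like and -0.83 for ILC1-like cells, against -2.05 and -1.96 over all cells. When cells were classed one by one it was -1.39 and -0.91, and at the higher clustering resolution it was -0.61 and -1.82, so the size of the difference for NK-like cells depends on the clustering. Clusters that no marker list named held 36.9% of the KO cells and 15.4% of the HET cells. Among them was a cluster with hemoglobin genes, Gzmb, Tcrg-C4 and Cd7 among its leading genes (12.9% and 1.20%). That cluster is not counted in the NK-like, ILC1-like and innate-like T-like shares. In the tumor NK1.1+ sort the clusters without a name held 13.6% of the KO cells and 24.1% of the HET cells. Most of these were a cluster with Klra9 among its leading genes (4.61% of KO and 11.3% of HET cells) and a cluster with Klra1, Klra7, Klrc1 and Trdc among them (3.54% and 9.89%). Neither is counted in the NK-like and ILC1-like shares or in the shares among those classes and innate-like T-like cells.

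**Figure D2:**
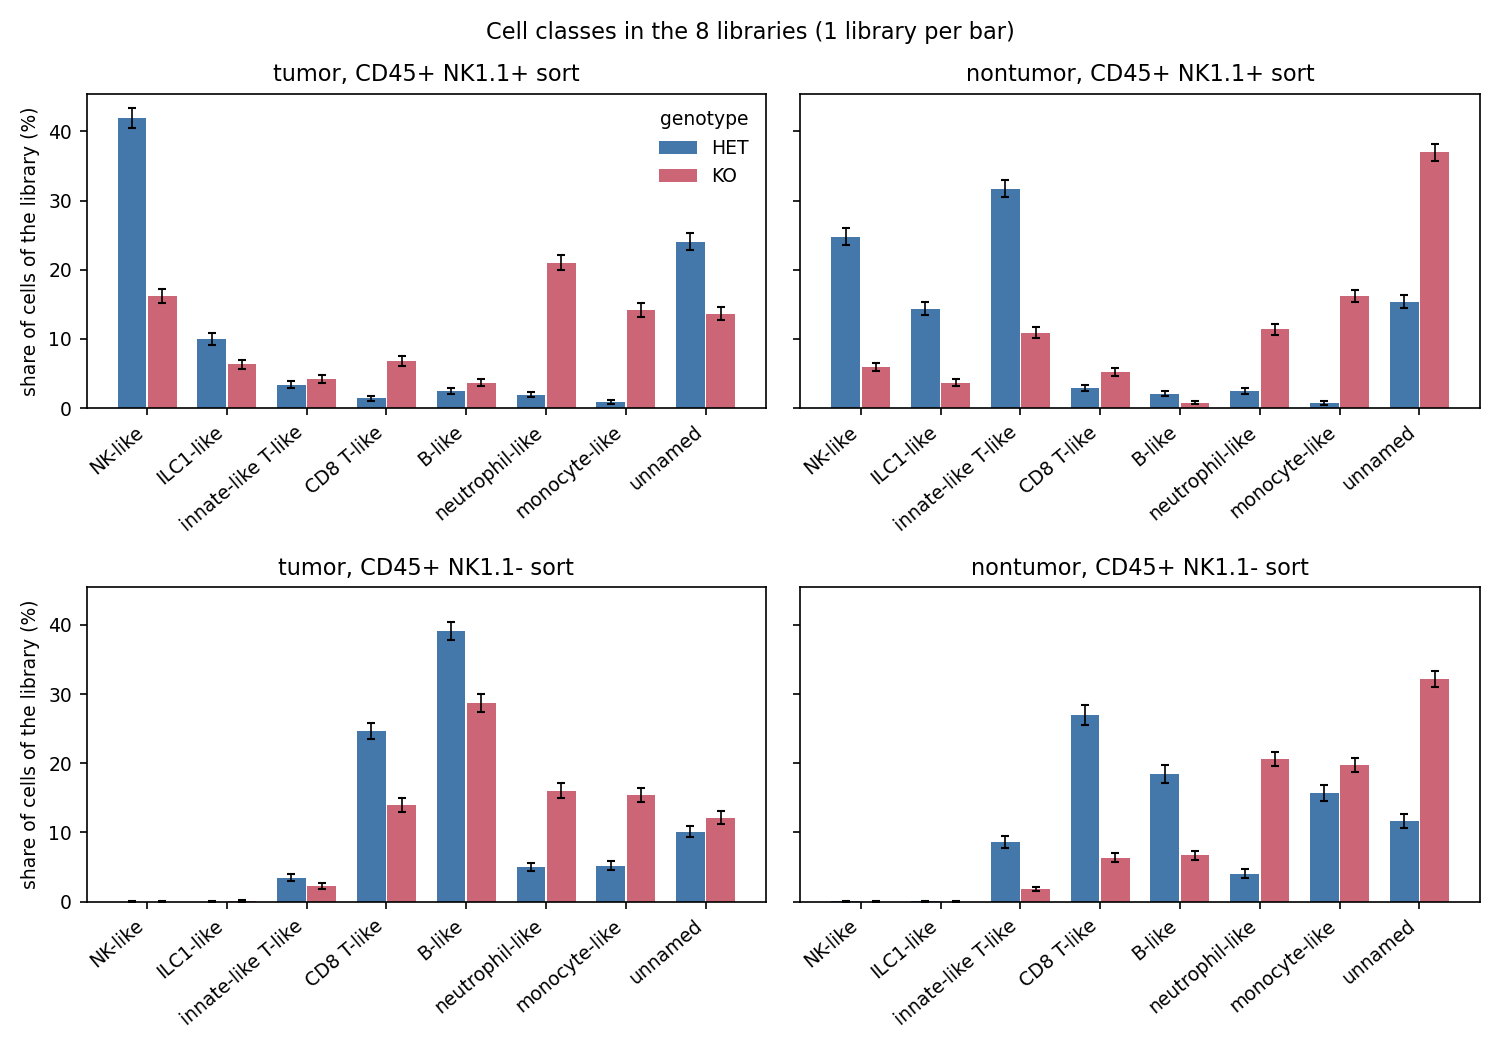
Share of the cells of each of the 8 libraries (y axis, percent) in 7 named classes and in clusters without a name, with HET in blue and KO in red; bars are single libraries and error bars are exact 95% intervals for counting error. NK-like cells are 41.9% of the tumor NK1.1+ HET library and 16.2% of the KO library, while neutrophil-like cells are 1.92% and 21.0%.

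Tumor NK-like cells of the KO library (836 cells, against 2012 in HET) showed lower levels of Cd69, Zfp36 and Myc and of the activating receptor list, with cytotoxic effector transcripts near or slightly above HET. Cd69, an early activation and retention marker (ENSMUSG00000030156), was 103 CPM in KO and 245 CPM in HET (log2 ratio -1.24, -1.41 to -1.08). Zfp36, an mRNA decay factor induced on activation, was 151 and 463 CPM (-1.62, -1.75 to -1.49), and Myc, a driver of lymphocyte growth, was 26.8 and 82.6 CPM (-1.62, -1.94 to -1.31). Ifng, the main effector cytokine of NK cells (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), was 373 and 508 CPM (-0.44, -0.53 to -0.36). Gzmb, a granzyme that kills target cells (ENSMUSG00000015437), was 1196 and 995 CPM (0.27, 0.21 to 0.32), 1.20 times higher in the KO library.

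By size, 90 of 5231 eligible genes were at least 2.0 times higher in the KO library and 19 were at least 2.0 times lower. Of the 83 higher genes open to naming, 48 had less than 50% of their level covered by free RNA. The highest ratios belonged to transcripts of other cells: Ighg2b and Ighg1, the immunoglobulin constant regions of plasma cells, and the neutrophil genes Ngp (66.7 against 2.94 CPM, 4.48), Lcn2 (4.22), Il1r2 (4.06), Camp (4.03) and Retnlg (3.82), together with the macrophage gene Chil3 (3.70). Ighg2b had 313 UMIs in the KO cells and 2 in the HET cells (8.45, 6.90 to 11.82). Prg2, an eosinophil granule protein, had 183 UMIs in the KO cells, of which 180 lay in 1 cell. Neutrophil RNA in solution, estimated from the neutrophil list, covered 40.9% of the Ifitm1 counts of these cells; for Ngp and the other genes of that list a high coverage is built into the estimate. Ifitm1 (153 against 7.21 CPM, 4.40), Ifitm2 (2.69) and Ifitm3 (2.22), antiviral membrane proteins that are also abundant in myeloid cells, were all higher. Beside Zfp36, Myc and Cd69, the lowest ratios were those of the heat-shock genes Hspa1a (-1.24) and Hspa1b (-1.17), the stress factor Atf3 (-1.19), Ctla2b (-1.14), Mri1 (-1.14), the lymphocyte GTPase Gimap7 (-1.13) and Igha, a plasma cell constant region (-1.12).

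The fixed gene lists described the same cells. The cytotoxic effector list had a median log2 ratio of 0.15 (-0.05 to 0.19) over 13 members, at percentile 99.3 of random lists; 0 members were 1.5 times higher and 1, Gzmm (-0.63), was lower. The list of NK activating receptors had a median of -0.35 (-0.38 to -0.21) over 15 members at percentile 0.0, with 3 members lower by 1.5 times, Slamf6 (-0.85), Cd226 (-0.73) and Ncr1. Klrk1, which encodes NKG2D, was 632 against 826 CPM (-0.39, -0.45 to -0.32). The cytokine and chemokine list had a median of -0.29 (-0.52 to -0.24) over 12 members at percentile 0.0, with Csf2 at -1.19 and Ccl4, a T cell and monocyte attractant, at -0.91. The dissociation stress list had a median of -0.30 (-0.39 to -0.23) with 6 of 20 members lower. The list of interferon-induced genes had a median of -0.24 (-0.31 to -0.11) over 23 members at percentile 0.0, with 3 lower, among them Ifit1 (-2.27) and Ifi47 (-0.74), and 3 higher, among them Ifi27l2a (1.00), 61.2% of whose counts free RNA covered.

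Other lists differed less. The inhibitory receptor list had a median of -0.12 (-0.20 to -0.01), with Klrc1, which encodes NKG2A, at -0.69. Lag3 was 10.5 against 6.09 CPM (0.79, 0.15 to 1.39), while Pdcd1, Tigit, Havcr2 and Ctla4 each stood below 6 CPM in both libraries, where no difference was detectable at this depth. The early and late maturation lists had medians of -0.01 and -0.07, and Klrg1, a late marker, was at -0.27 (-0.42 to -0.12). The tissue residency list had a median of 0.32 (0.14 to 0.43) over 7 members, with Il21r at 0.85 and Cd69 at the other end. The list of activation and metabolism had a median of 0.14 (0.09 to 0.19), with the glucose transporter Slc2a1 (0.81) higher and Myc lower, while Hk2 was at 0.88 but at -0.07 in cells thinned to equal depth. The list of the IL-27 receptor and pathway had a median of -0.11 (-0.22 to -0.01), the cell cycle list 0.15 (0.00 to 0.25) and the sex list 0.12 (-0.08 to 0.30).

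Lists of transcripts that other cells make were included to show RNA from those cells in the same NK-like cells of tumor. The neutrophil list had a median of 3.82 (3.53 to 4.14), and the inflammatory myeloid list 2.67 (2.46 to 2.87) with Acod1, an enzyme of activated myeloid cells, at 3.64. The class II list, which B cells and myeloid cells express, had a median of 0.96 (0.84 to 1.1), the B and plasma cell list 0.31 (0.02 to 0.71) and the tumor-associated macrophage list 0.21 (0.10 to 0.41). The myeloid list led by C1q genes had a median of -0.20 (-0.26 to -0.14) and the erythrocyte list -0.62 (-1.37 to -0.30). The regulatory T list had a median of 0.25 (0.11 to 0.41) and the naive and memory T list -0.01. The hepatocyte list was read from 2 members, Hp (3.04) and Trf (1.05), the Kupffer list from Id3 (1.02) and the endothelium list from Fcgr2b (-0.10).

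Gzma, Prf1 and Ncr1 were among the genes that set the NK-like cluster apart, so their levels depend on how cells were grouped. With these genes and the NK lists left out of the clustering, Prf1 (perforin, ENSMUSG00000037202, chromosome 10, 61297833 to 61304680) had a log2 ratio of 0.26 in tumor, Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981) 0.06 and Ncr1, an activating receptor (ENSMUSG00000062524), -0.63. In the clustering with all genes the values were 0.16, -0.05 and -0.64, so the direction for Gzma turned.

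**Figure D3:**
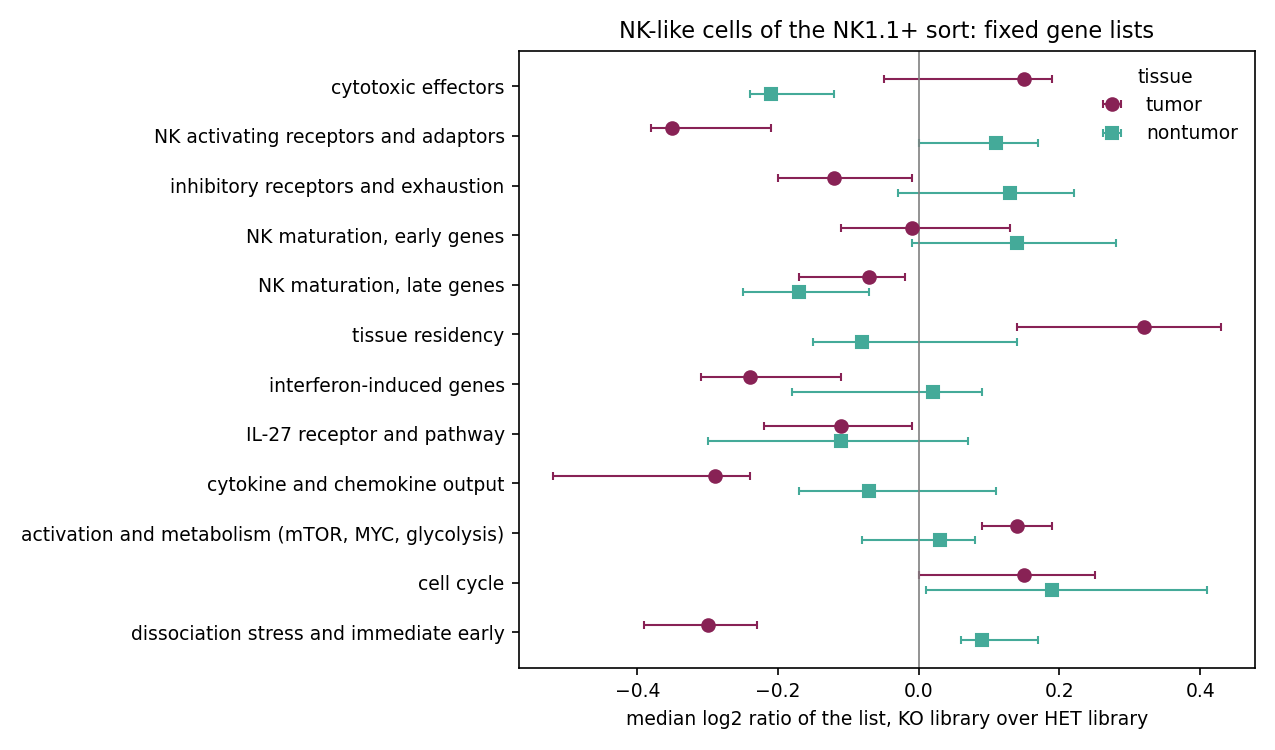
Median log2 ratio of KO over HET (x axis) for 12 fixed gene lists in NK-like cells of tumor (circles) and nontumor tissue (squares), 1 library per group; bars are 95% intervals for counting error. The activating receptor, cytokine and stress lists lie below 0 in tumor, at -0.35, -0.29 and -0.30.

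Nontumor NK-like cells of the KO library (394 cells, against 1323) had less Cxcl10 RNA and more Cd3g and Cd3e RNA. Cxcl10, an interferon-induced chemokine that attracts T and NK cells (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), was 18.0 CPM in KO and 112 CPM in HET (log2 ratio -2.61, -3.29 to -2.05), 6.10 times lower. Ifit1 (-1.88) and Isg15 (-1.03), both induced by interferon, were also lower, yet the interferon list as a whole had a median of 0.02 (-0.18 to 0.09). The cytotoxic effector list had a median of -0.21 (-0.24 to -0.12) over 12 members at percentile 0.2, with Serpinb9, a granzyme B inhibitor, at -0.70. Cd3g (1.66) and Cd3e (1.57), which belong to the T cell receptor complex, were higher in the KO library.

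The size rule took 38 of 5395 genes as higher and 28 as lower, and 27 of the 33 higher genes open to naming were mostly not covered by free RNA. Higher were the neutrophil and myeloid genes Ngp (7.59, 6.01 to 10.97, on 2 UMIs in HET), Lcn2 (3.58), Lyz2 (2.31), S100a8 (1.67) and S100a9 (1.59), then Cxcr6, a liver-homing chemokine receptor (2.19), Ifitm3 (2.13) and Inpp4b (1.58). Lower were Gramd3 (-1.63), the nuclear lamina gene Lmna (-1.55), Spp1, which encodes osteopontin (-1.51), Nfkbie, an inhibitor of NF-kB (-1.34), Rnf157 (-1.27), Dab2ip (-1.17), Epb41l2 (-1.16) and the drug exporter Abcb1b (-1.16). Ifng was at -0.21 (-0.30 to -0.11), Gzmb at -0.07 (-0.16 to 0.01) with no settled direction, since it was 0.22 (0.09 to 0.33) among cells with no Cd3 UMI and 0.13 (0.06 to 0.20) when cells were classed one by one, Klrk1 at 0.01 and Klrg1 at -0.27 (-0.51 to -0.04). Clustered without the genes in question, Prf1 was at -0.54, Gzma at -0.09 and Ncr1 at 0.21. The activating receptor list had a median of 0.11 (0.00 to 0.17), the late maturation list -0.17 (-0.25 to -0.07), with Irf8 (-0.84) and Prdm1 (-0.74) lowest, and the stress list 0.09 (0.06 to 0.17). Among NK-like cells with no Cd3 UMI, 191 in KO and 751 in HET, the cytotoxic median was -0.02 and the late maturation median 0.06, while Prf1 was at -0.32.

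Set against each other, the tissues gave differences of the log2 ratios (tumor minus nontumor) of 0.78 for Prf1, 0.34 for Gzmb, -0.77 for Ncr1, -0.39 for Klrk1 and -1.11 for Il27ra in NK-like cells. Among cells with no Cd3 UMI the difference was 0.54 for Prf1, 0.14 for Gzmb and -1.96 for Il27ra. For lists over the members measured in both tissues, the difference was 0.25 for cytotoxic effectors, -0.39 for activating receptors, -0.27 for interferon targets and -0.37 for dissociation stress. The interferon difference was -0.03 in thinned cells and 0 in the clustering without list genes, so it is not settled. With 1 library per group these differences were not tested. Of genes past the size rule, 14 were higher in KO in both tissues, led by Ngp, Lcn2, Ifitm3, Lyz2 and S100a8, and 0 were lower in both. S100a8 and Lyz2 are neutrophil and myeloid genes whose tumor ratios were 3.44 and 2.13.

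ILC1-like cells of the KO libraries held more granzyme B transcripts in both tissues. In tumor, Gzmb (chromosome 14, 56258838 to 56262260) was 937 CPM in KO (326 cells) and 361 CPM in HET (481 cells), a log2 ratio of 1.37 (1.27 to 1.49). In nontumor tissue it was 2420 CPM in KO (242 cells) and 1097 CPM in HET (766 cells), 1.14 (1.07 to 1.21). Gzma was 0.21 (0.14 to 0.29) in tumor, where it turned to -0.01 among cells with no Cd3 UMI, and 0.74 (0.68 to 0.80) in nontumor tissue. Gzmc, a further granzyme, was 1.59 (1.35 to 1.83) and 2.01 (1.73 to 2.29). Innate-like T-like cells showed the same direction for Gzmb, 1.52 (1.24 to 1.83) in tumor and 1.09 (0.98 to 1.21) in nontumor tissue. The tumor ratio was 0.52 (0.37 to 0.67) when cells were classed one by one, and free RNA covered 28.7% of the HET level. Prf1 went the other way in ILC1-like cells, -0.28 (-0.52 to -0.05) in tumor and -0.35 (-0.61 to -0.10) in nontumor tissue, but the tumor ratio turned to 0.02 when cells were classed one by one.

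**Figure D4:**
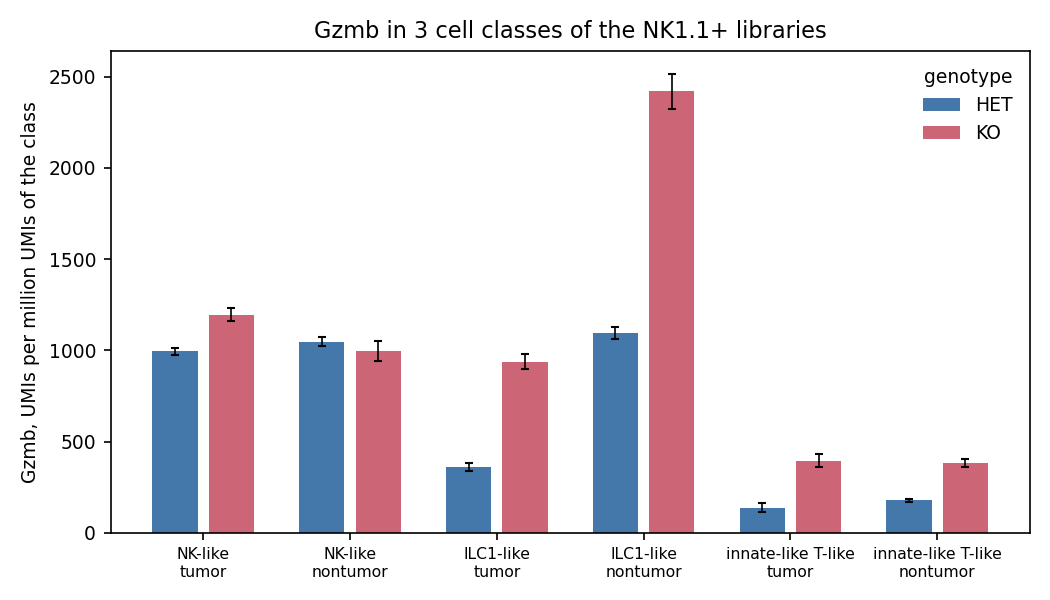
Gzmb level (y axis, CPM of the class) in NK-like, ILC1-like and innate-like T-like cells of the NK1.1+ libraries, HET in blue and KO in red, 1 library per bar with exact Poisson 95% intervals. ILC1-like cells of nontumor tissue hold 2420 in KO and 1097 in HET, while NK-like cells of nontumor tissue hold 997 and 1047.

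In tumor ILC1-like cells, 47 of 5117 genes were past the size rule as higher (25 of 43 nameable genes mostly not covered by free RNA) and 20 as lower. Higher were Ighg2b (90.2 CPM against 0 UMIs, for which the upper bound was 1.30 CPM), Camp (4.59), Retnlg (4.58), Ngp (4.40) and Ifitm1 (4.20). Lower were Ifit1 (-2.76), the Notch target Hes1 (-1.87), Cxcl10 (67.1 against 238 CPM, -1.82, -2.10 to -1.57), Tnf, an inflammatory cytokine (-1.73), and Mri1 (-1.46). The tissue residency list had a median of 0.40 (0.33 to 0.47) at percentile 100, with the integrin Itga1 at 0.74. The cell cycle list had a median of 0.40 (0.22 to 0.57), with Stmn1 at 1.09, whereas cytokine output (-0.29, -0.35 to -0.19), interferon targets (-0.20, -0.37 to -0.13) and stress genes (-0.28, -0.38 to -0.22) had medians below 0. Cytotoxic effectors had a median of -0.03 (-0.13 to 0.09) despite Gzmb and Gzmc, and activating receptors -0.13 (-0.27 to -0.08), which was -0.04 in the clustering without list genes. Klrk1 was at -0.44 (-0.53 to -0.34) and Ifng at -0.21 (-0.36 to -0.07).

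In nontumor ILC1-like cells, 23 of 5365 genes were higher (18 of 22 nameable genes mostly not covered by free RNA) and 34 were lower. The NK receptor genes Klra7 (2.09) and Klra8 (1.94) and the T cell receptor gamma constant gene Tcrg-C2 (1.99) were among the highest, beside Lyz2 (2.08) and S100a8 (2.03). Ccdc184 (-2.74), the transcription factor Crem (-1.75), Cxcl10 (68.6 against 218 CPM, -1.66, -2.04 to -1.32), the activation marker Cd83 (-1.58) and Cdip1 (-1.57) were lowest. The early maturation list had a median of -0.30 (-0.46 to -0.08), with Emb (-0.99) and Il7r, the IL-7 receptor (-0.63), lowest. The cell cycle median was 0.57 (0.25 to 0.76), with Stmn1 at 1.40, and the interferon median -0.01 (-0.20 to 0.08). Ifng was 956 against 723 CPM (0.40, 0.30 to 0.51) and Ctla4, an inhibitory receptor, was at -1.17 (-2.33 to -0.28). Across both tissues, 12 genes were higher in KO and 1, Cxcl10, was lower.

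In innate-like T-like cells of tumor (218 KO and 164 HET cells), Ccl3, a monocyte attractant, was at -1.91 (-2.47 to -1.39), of which free RNA covered 68.9% of the higher level, and Ifng at 0.15 (-0.06 to 0.36). In nontumor tissue (716 and 1693 cells) Cxcl10 was at -2.14 (-2.85 to -1.55), the small GTPase Rrad at -1.50, the stress sensor Ern1 at -1.23 and the interferon-induced GTPase Iigp1 at -2.82. The interferon list had a median of -0.27 (-0.32 to -0.13) at percentile 0.0. The highest ratios belonged to Ngp (7.24), Camp (7.16, 5.81 to 9.67, on 3 UMIs in HET) and Ighg2c (6.52), transcripts of neutrophils and plasma cells.

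The comparison of tumor with nontumor tissue in HET animals asks how innate lymphocytes of the tumor differ from those of the surrounding liver where 1 copy of the targeted gene is kept. NK-like cells of tumor (2012, against 1323) held cytotoxic transcripts slightly below the nontumor level and had less Ifng and less stress RNA. Ifng was 508 against 920 CPM (log2 ratio -0.86, -0.91 to -0.80), Gzmb was at -0.07 (-0.12 to -0.03), and the cytotoxic list had a median of -0.08 (-0.11 to -0.07). Klf2, a factor that keeps lymphocytes quiescent and circulating, was 1491 against 3058 CPM (-1.04, -1.07 to -1.01). The stress list had a median of -0.71 (-0.75 to -0.66) with 12 of 20 members lower, among them Hspa1a (-2.36), Hspa1b (-1.99), Jun (-1.49), Fos (-1.47), Dnajb1 (-1.28) and Fosb (-1.17), and the interferon list a median of -0.20 (-0.31 to -0.16). Further lower genes were Ifit1 (-1.20), Cd3e (-1.19), Ly6a (-1.19) and Tcrg-C4 (-1.13).

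By size, 17 of 5185 genes were higher in tumor NK-like cells and 12 were lower, and 4 of the higher genes were mostly not covered by free RNA. The highest were the macrophage complement genes C1qa (2.96), C1qb (2.60) and C1qc (2.54), the lipid carrier Apoe (1.76), Igha (1.67), the class II genes H2-Eb1 (1.48), H2-Aa (1.45) and H2-Ab1 (1.33), and Wfdc17 (1.30), with free RNA covering 66.0% of the C1qa and 90.9% of the H2-Aa counts. Genes little covered by free RNA were AY036118 (1.48), Crem, a cAMP-responsive factor (1.25), Pmepa1, a TGF-beta target (1.11), and Fam177a (1.02).

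ILC1-like cells differed more between the tissues, with 70 of 5521 genes higher in tumor and 83 lower. Gzmb was 361 against 1097 CPM (-1.60, -1.70 to -1.50), Ifng 349 against 723 CPM (-1.05, -1.16 to -0.95) and Gzma was at -0.62 (-0.68 to -0.56). Vegfa, the angiogenic factor, was 59.3 against 9.49 CPM (2.63, 2.13 to 3.18), followed by C1qa (2.20), Crem (2.00), Mef2c (1.96) and the NF-kB subunit Rel (1.82). The matrix protease Mmp9 (-3.25), Hspa1a (-2.84), Zmat4 (-2.78), Hspa1b (-2.49) and Jun (-2.26) were lowest. The residency list had a median of -0.52 (-0.62 to -0.42), with Itga1 (-1.36) and Cxcr6 (-1.24) lowest, the interferon list -0.48 (-0.56 to -0.39), the cytotoxic list -0.35 (-0.40 to -0.26) and the stress list -0.95 (-1.06 to -0.78). Ctla4 (1.15, 0.76 to 1.54) and Tigit (1.38, 0.32 to 2.55), inhibitory receptors, were higher in tumor, and Lag3 was at -0.62 (-0.88 to -0.37). Innate-like T-like cells were 31.7% of nontumor and 3.42% of tumor NK1.1+ HET cells, 9.27 times lower in tumor.

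The same comparison in KO animals set deep tumor libraries against shallow nontumor libraries. In NK-like cells 223 of 5024 genes were higher in tumor and 97 were lower, and in ILC1-like cells 184 of 3936 were higher and 84 were lower. Median UMIs per cell were 3771.5 in tumor and 2788.5 in nontumor NK-like cells, and 5651.5 and 3727.5 in ILC1-like cells, so single genes of this comparison are not named.

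In the NK1.1- sort of tumor, the KO library held more neutrophil-like and monocyte-like cells and fewer CD8 T-like, regulatory T-like and B-like cells than the HET library. Neutrophil-like cells were 4.98% (4.42 to 5.59) of 5562 HET cells and 16.0% (15 to 17.1) of 4637 KO cells, 3.21 times higher, and monocyte-like cells 5.20% and 15.4%, 2.95 times higher. CD8 T-like cells were 24.6% and 13.9% (1.77 times lower), which lay in the cluster marked by Pdcd1 and Tox (17.7% and 6.79%), while the cluster led by Dapl1 and Lef1 was level (6.96% and 6.77%). An unnamed cluster led by Il17a, with Icos and Ctla4 among its leading genes, went the other way, 6.11% and 8.43%. Regulatory T-like cells were 5.30% and 3.00% (1.77 times lower) and B-like cells 39.1% and 28.7% (1.36 times lower). In nontumor tissue neutrophil-like cells were 3.99% of 3736 HET cells and 20.6% of 6116 KO cells, CD8 T-like cells 27.0% and 6.33%, and regulatory T-like cells 5.92% and 1.11%. These classes joined clusters of unlike depth: of the monocyte-like cells, 94.7% (NK1.1+) and 84.4% (NK1.1-) in nontumor KO came from a cluster with a median of 962.0 UMIs, whereas nearly all monocyte-like cells of tumor KO came from a cluster with a median of 10066.0 UMIs. Neutrophil-like cells of nontumor KO likewise came mostly from a shallow cluster marked by Camp and Ngp, with a median of 845.5 UMIs. Leaving such a cluster out of its class alone lowers the KO share by construction and gives no direction. Among cells of 2000 UMIs or more, which in the nontumor NK1.1- sort were 98.1% of HET and 30.04% of KO cells, neutrophil-like cells were 3.82% of HET and 8.44% of KO cells in that sort (log2 ratio 1.14, 0.80 to 1.48, against 2.36 over all cells) and 2.20% and 3.16% in the NK1.1+ sort (0.53, 0.09 to 0.96, against 2.18), and monocyte-like cells were at 0.12 (-0.09 to 0.32) in the NK1.1- and 4.12 (3.50 to 4.86) in the NK1.1+ sort. So the size of these nontumor differences depends on which cells are counted, and monocyte-like cells of the nontumor NK1.1- sort have no settled direction. In tumor the same cells gave 1.71 and 3.53 for neutrophil-like and 1.57 and 4.27 for monocyte-like cells in the NK1.1- and NK1.1+ sorts. The nontumor CD8 T-like and regulatory T-like shares above are over all cells. The KO library held 387 and 68 such cells of any depth, and 1837 cells of 2000 UMIs or more. Its CD8 T-like cells had a median of 3619 UMIs, against 1101 over the library. So KO cells of few UMIs may lower these shares, and the size of both differences is not settled.

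CD8 T-like cells of the cluster marked by Pdcd1 and Tox, genes of chronically stimulated T cells, had less granzyme A RNA in KO. In tumor (315 KO and 982 HET cells) Gzma was 262 against 1190 CPM (log2 ratio -2.19, -2.32 to -2.06), Ccl3 was at -1.83, Gzmb at -1.15 (-1.30 to -0.99), Lag3 at -1.27 (-1.70 to -0.89), Havcr2, which encodes TIM-3, at -1.35 (-2.53 to -0.45), Ctla4 at -0.99 (-1.26 to -0.73) and Tigit at -0.80 (-2.0 to 0.14). Pdcd1, whose level depends on the grouping because it marks the cluster, was at -0.89 (-1.20 to -0.60) in tumor and -1.63 (-2.62 to -0.87) in nontumor tissue. The inhibitory receptor list as a whole had a median of -0.14 (-0.39 to -0.02) over 13 members at percentile 22.0 in tumor and -0.13 (-0.84 to 0.04) over 11 members at percentile 27.6 in nontumor tissue, with 5 members lower by 1.5 times in each. In nontumor tissue (197 and 588 cells) Gzma was at -2.18 (-2.42 to -1.97), Lag3 at -2.11, Ctla4 at -2.49, and Gzmb at 0.38 (0.24 to 0.53). Ifng was at 0.14 (-0.01 to 0.30) in tumor and 0.93 (0.78 to 1.07) in nontumor tissue. The signaling regulator Rgs16 (-1.51 in tumor, -2.07 in nontumor tissue) was lower in both, and Trdc, the T cell receptor delta constant region, was at 3.14 in tumor, where Trat1 (1.83) and Irs2 (1.73) followed. The naive and memory T list had a median of 0.69 (0.53 to 0.78) in tumor, with the chromatin organizer Satb1 at 1.39, and -0.33 (-0.48 to -0.04) in nontumor tissue. The interferon list had a median of -0.36 (-0.48 to -0.23) in tumor and 0.01 (-0.18 to 0.11) in nontumor tissue.

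Monocyte-like cells of the tumor NK1.1- sort (712 KO and 289 HET cells) held more inflammatory and fewer interferon-induced transcripts in KO. The inflammatory myeloid list had a median of 1.14 (1.09 to 1.34) with 14 of 17 members at least 1.5 times higher, among them Ptgs2, the inducible prostaglandin synthase (1.89), Il1a (1.76), Il1b (4138 against 1518 CPM, 1.45, 1.40 to 1.49) and Tnf (1.12). Areg, a growth factor of tissue repair, was 122 against 13.6 CPM (3.15, 2.70 to 3.69), Csf3, which drives neutrophil production, was at 2.72 (1.99 to 3.66), Il6 at 1.75 and Il10 at 1.62. The interferon list had a median of -0.36 (-0.53 to -0.34) with 10 of 28 members lower, led by Ifit3 (-1.79), and Gbp5 at 1.21 was the exception. The nontumor ratio of Il6 in this class and sort was past the size rule in the other direction, with KO cells mostly from a cluster of few UMIs. In tumor the lipase Lpl was at -2.50 and the muscle-type enolase Eno3 at -1.78. Regulatory T-like cells (139 and 295 cells) had higher Tnfrsf9, an activation receptor (1.35, 0.94 to 1.77), Areg (1.24) and Pdcd1 (0.90, 0.50 to 1.30), a regulatory T list median of 0.55 (0.37 to 0.71) and an interferon median of -0.45 (-0.62 to -0.29), with Tap1 at -1.02. B-like cells (1332 and 2175 cells) had lower Hspa1b (-2.23) and Hspa1a (-2.16) and higher Cd80 (1.20) and Cd86 (0.87), which costimulate T cells.

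Neutrophil-like cells of the same sort (743 and 277 cells) were a different mix of clusters in the KO library. Clusters led by granule genes such as Camp, Ngp and Ltf gave 105 and 20 of the KO cells and 14 and 0 of the HET cells. For the class as a whole 164 genes were higher in KO, but within its largest cluster (616 KO and 262 HET cells) 30 were, and the list values below describe the mix. The cell cycle list had 15 of 15 members at least 1.5 times higher in KO, whereas within the largest cluster its 2 measured members were at 0.0 and -0.14. In the class, Rrm2 stood at 52.0 CPM against 0 UMIs and Nusap1 at 47.1 CPM against 0 UMIs, for each of which the upper bound in HET was 3.72 CPM, and Mki67, chosen after its values were seen, was 73.3 against 5.04 CPM. Elane, the granule elastase made by immature neutrophils, was 188 CPM against 0 UMIs. Lower were the chemokine Cxcl3 (-1.75), Scnn1a (-1.60) and Il15, which sustains NK cells (-1.59). The interferon list had a median of -0.54 (-0.76 to -0.40) in the class and -0.10 (-0.34 to 0.03) within the largest cluster.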

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

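The tests of free RNA for Gzmb, of read depth, of Siglech and of marker lists were chosen only after the results were seen, as were the clustering without list genes and the selection of cells with no Cd3 UMI. Every difference between tissues below was picked because its direction was opposite in the 2 tissues, and with 1 library per group none of these differences was tested.

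In NK-like cells the ratio of KO to HET lay on opposite sides of 0 for several genes. Prf1, perforin, was 0.16 in tumor and -0.63 in nontumor tissue, a difference of 0.78, and 0.26 and -0.54 in the clustering without it. Ncr1, an activating receptor, was -0.64 and 0.13, a difference of -0.77. The drug exporter Abcb1b was 1.09 and -1.16, a difference of 2.25. The dissociation stress list was -0.30 and 0.09, a difference of -0.37 over the members measured in both tissues.

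In ILC1-like cells Ifng was -0.21 in tumor and 0.40 in nontumor tissue, a difference of -0.61. The lipid receptor Gpr55 was 1.23 and -1.27, a difference of 2.5. Klra8, an NK receptor, was -1.04 and 1.94, a difference of -2.98, but its tumor ratio was 0.22 in the clustering without list genes and 0.71 with a class per cell. The regulatory T list was 0.11 and -0.87, a difference of 0.97, and the inflammatory myeloid list 0.93 and -0.22, a difference of 0.27 over the members measured in both tissues. Gzmb in the CD8 T-like cluster marked by Pdcd1 and Tox was -1.15 and 0.38, a difference of -1.53. The share of innate-like T-like cells in the NK1.1+ sort was 0.30 and -1.54, a difference of 1.84. The nontumor value is over all cells, of which 36.6% in KO and 96.5% in HET held 2000 UMIs or more. KO cells of the class had a median of 3841 UMIs, so the size of this difference depends on which cells are counted.

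Clusters without a name held many cells of the nontumor KO libraries. A cluster led by the proliferation genes Pclaf, Top2a and Mki67 held 8.03% of NK1.1+ and 10.9% of NK1.1- cells in KO, against 0 of 5334 NK1.1+ cells and 0.883% of NK1.1- cells in HET. A cluster led by hemoglobin genes and by Ctsg, Elane, Prtn3 and Mpo, granule genes of myeloid progenitors, held 6.64% and 12.3%, against 0.412% and 0.0268% in HET. A cluster led by hemoglobin genes, Hspa1b and Gzmb held 12.9% of NK1.1+ KO cells, against 1.20% in HET. Tcrg-C4, Cd7 and Rgs1 were also among its leading genes, and its median was 749 UMIs. Its best marker list was that of ILC1, at a mean log2 fold of 0.94, under the minimum of 1.0. It is not counted in the NK-like, ILC1-like or innate-like T-like shares, so part of their nontumor differences may lie in this cluster.

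Gzmb was higher in ILC1-like cells of KO in both tissues, by 1.37 in tumor and 1.14 in nontumor tissue. Free RNA covered at most 2.41% of the Gzmb UMIs of the KO cells, too little to make the difference. Many cells of the class held Cd3 RNA: 184 of 326 KO and 303 of 481 HET cells of tumor, and 73 of 242 KO and 334 of 766 HET cells of nontumor tissue, had no Cd3 UMI, so the class may hold T cells. Among the cells with none the log2 ratio was 1.67 (1.52 to 1.83) in tumor and 1.06 (0.92 to 1.20) in nontumor tissue, the latter on fewer KO cells than the minimum of 100 set for comparisons. In the clustering without Gzmb and the list genes it was at least 0.96. These values argue against cells with detected Cd3 RNA, and against placement by the genes left out, as the whole source of the difference. A T cell can lack a Cd3 UMI at this depth, so T cells are not excluded. A CD8 T-like cluster with Klra7 and Gzmb among its leading genes was larger in KO. It held 264 KO and 21 HET cells in the tumor NK1.1+ sort, and 298 and 113 in nontumor tissue. Whether such cells lie in the ILC1-like class was not tested. A higher Gzmb level in ILC1-like cells of KO animals stays a hypothesis that may hold, since animal, library and genotype are the same split here.

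Mri1 and Gm42031, both near Il27ra, were lower in KO in every class comparison in which they had enough UMIs, though comparisons from the same libraries are not independent. A candidate explanation is a stretch of another strain's chromosome carried with the targeted allele, in which case more neighbors would differ. The share of genes within 5 Mb that differed by 1.5 times with 1 sign lay at percentile 49.5 of 6406 windows of the genome, and 0 of 58 neighbors did. Mri1 misses that rule too, since its ratio nearest to 0 was -0.14. By sign alone, which Mri1 meets, 2 of 58 neighbors did, and 79.2% of windows held a smaller share. Between Mri1 and Gm42031, Gadd45gip1 (median -0.68) and Trmt1 (-0.38) were each lower in KO in 12 of 13 comparisons. By a looser rule set after these values were seen, 1 sign in all comparisons or all but 1 and a median of 1.5 times, 1 neighbor passed, and 24.0% of windows held as many or more. That looser rule was met by 46 of 7567 genes and the first rule by 3, so the first had little room. The 3 were Gm42031, Hbb-bs on chromosome 7 (median -1.76 over 7 comparisons), a transcript of red cells, and Gm47283 on the Y chromosome (1.36, higher in KO in 15 of 15), the last 2 named after their values were seen. Such differences on other chromosomes keep a difference of strain or animal beyond this region open too. A short stretch, an effect of the targeting on nearby transcripts and a biological effect cannot be told apart.

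Most barcodes of the nontumor KO libraries had few UMIs. Fewer reads per cell would cut all cells of a library alike. In the NK1.1+ sort the library median was 3.789 times lower in KO, but that of innate-like T-like cells was 1.288 times lower, and 230 of these KO cells reached the HET median of the class, 10.64 times the most that the HET class cut by 3.789 times would give if every KO cell were of the class. So fewer reads could not be the whole cause there. In the NK1.1- sort the medians were 5.294 and 1.207 times lower, but 24 cells, 0.343 times that most, exclude nothing. So this class cannot tell fewer reads from other causes in that library. B-like cells, 1 cluster, had medians of 2904.5 UMIs in KO and 4338.5 in HET there, also a smaller fall than 5.294 times. The same test was not run on them. Droplets with free RNA alone would carry the mix of the library, but among low-UMI barcodes those with a Siglech UMI held the other markers of plasmacytoid dendritic cells at a level at least 7.62 times that of all of them. Neutrophil RNA in the low-UMI barcodes like those cells, at 0.949 (NK1.1+) and 0.463 (NK1.1-) times the level in all barcodes, did not meet the bound set in advance for both libraries and excludes nothing. At least 53.4% of low-UMI barcodes of the named classes held more UMIs of a marker list than draws from the mix of all barcodes, which gave at most 0.24%. Clusters were named by these same lists, so that share is partly set by the naming. Over all low-UMI barcodes of the 2 libraries, which the naming does not select, it was 36.5% and 40.9%. For the unnamed clusters it was as low as 9.10%, a low value that the naming also favors. Free RNA may make up part of them and cannot be told apart from cells of low RNA content. Damaged cells, handling and genotype stay open and were not tested.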

How the results depend on the processing

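Alternatives chosen only after the data were seen were the clustering without leading genes and NK lists, cells of 2000 UMIs or more, shares among NK-like, ILC1-like and innate-like T-like cells, classes without their cluster of fewest UMIs, cells with no Cd3 UMI, free RNA subtracted, thinned cells for list medians, and all settings but TMM and median-of-ratios factors for differences between tissues. A value counts as moved when it left its counting interval, or, for a number of genes, when it differed by over 1.5 times, and as reversed when it changed sign and that interval did not hold 0. No paired analysis was made: each group has 1 library, and the labels give no replicate numbers. The aggregated matrices were not run for the NK1.1- libraries. Values are log2 ratios of KO to HET unless stated, and the cause of a move was not tested except where the alternative's construction shows it.

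Of 46 alternative class shares 30 stayed, 15 moved and 1 reversed. The NK-like share in nontumor tissue (-2.05) was -2.40 without doublet removal, -1.57 with the stricter cell filter, -2.30 at lower and -0.61 at higher resolution, -1.39 with a class per cell, -2.28 in the clustering without list genes and -1.18 among cells of 2000 UMIs or more. The ILC1-like share in nontumor tissue (-1.96) was -1.67 with the stricter filter, -0.91 with a class per cell, -1.72 without list genes and -0.83 among cells of 2000 UMIs or more. In tumor the ILC1-like share (-0.67) was -0.38 without list genes. Among NK-like, ILC1-like and innate-like T-like cells alone, the NK-like share was -0.32 in tumor and -0.26 in nontumor tissue and the ILC1-like share -0.18 in nontumor tissue, and in tumor it reversed to 0.38; this alternative leaves out the myeloid and other cells of the sort by construction.

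The number of genes past the size rule stayed within 1.5 times in 48 of 96 alternatives, and a looser or stricter rule changes it by construction. With at least 30 UMIs and no CPM minimum it was 259 higher and 142 lower for NK-like cells of tumor, 207 and 144 in nontumor tissue and 98 and 87 for tumor against nontumor in HET, and for ILC1-like cells 148 and 101, 143 and 162, and 158 and 257. With at least 300 UMIs it was 42 higher for NK-like cells of tumor, 9 higher and 12 lower in nontumor tissue, and for ILC1-like cells 16 and 8, 9 and 7, and 36 and 44. At a ratio of 1.5 it was 241 and 104, 226 and 204, and 48 and 60 for NK-like cells, and 170 and 112, 127 and 203, and 271 and 344 for ILC1-like cells. At a ratio of 3 it was 40 and 3, 9 and 4, and 5 and 2 for NK-like cells, and 23 and 4, 10 and 4, and 13 and 19 for ILC1-like cells. With free RNA subtracted 58 genes were higher for NK-like cells of tumor, and 5 for tumor against nontumor in HET, where the aggregated matrix gave 11.

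Of 176 alternative medians of the cytotoxic, activating, interferon and stress lists 159 stayed and 17 moved. The cytotoxic median of nontumor NK-like cells (-0.21) was -0.29 with TMM and with median-of-ratios factors, -0.27 in the aggregated matrix, -0.07 with at least 30 UMIs and -0.02 among cells with no Cd3 UMI. Their stress median (0.09) was 0.01 with either factor and 0.20 with no Cd3 UMI. In the aggregated matrix the stress median was -0.41 in NK-like and -0.40 in ILC1-like cells of tumor and 0.05 in ILC1-like cells of nontumor tissue (0.01), which became -0.05 as a mean per cell and -0.06 in thinned cells. The activating median of tumor ILC1-like cells (-0.13) was -0.06 as a mean per cell, -0.05 in thinned cells and -0.04 without list genes, and in nontumor tissue it was -0.15 without list genes. Of 419 alternatives for other lists 364 stayed, 50 moved and 5 reversed. In NK-like cells of tumor the late maturation median turned to 0.02 without list genes, the IL-27 pathway median to 0.03 with no Cd3 UMI and the inflammatory median to -0.93 with free RNA subtracted. The class II median for tumor against nontumor in HET turned to -0.06 with free RNA subtracted, and the late maturation median of nontumor NK-like cells to 0.06 with no Cd3 UMI.

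Il27ra over all cells of a library was -1.54 in tumor, against -0.89 in NK-like and -0.91 in ILC1-like cells, and -0.44 in nontumor tissue, against 0.21 in NK-like cells; all cells include other mixtures of classes. Of 99 alternatives for the differences between tissues of 5 genes and 4 lists in NK-like cells 89 stayed and 10 moved. Among cells with no Cd3 UMI the difference for Il27ra (-1.11) was -1.96 and that for Prf1 (0.78) was 0.54, and with a class per cell that for Prf1 was 0.94. The difference for Gzmb (0.34) was 0.16 in the aggregated matrix, 0.19 with a class per cell and 0.14 with no Cd3 UMI. For interferon targets (-0.27) it was -0.03 in thinned cells and 0 without list genes, and for stress (-0.37) it was -0.49 in the aggregated matrix and -0.26 in thinned cells. With no Cd3 UMI the nontumor ratio of Il27ra (0.21) was 0.98 and that of Prf1 (-0.63) was -0.32.

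Of 2161 alternatives for single genes 1853 stayed, 294 moved and 14 reversed. Sign also changed in 9 of the moved and 19 of the values that stayed, all from ratios whose interval held 0. Of these, Gzmb in nontumor NK-like cells (-0.07) was above 0 in 7 alternatives, from 0.02 to 0.22. Gzma in tumor NK-like cells (-0.05) turned to 0.01 in the aggregated matrix, 0.03 as a mean per cell, 0.04 with a class per cell and with no Cd3 UMI, and 0.06 in thinned cells and without list genes, so its direction is not settled. Hk2 there turned to -0.07 in thinned cells and S100a8 to -4.87 with free RNA subtracted, by construction. With no Cd3 UMI, Gzma and Klrg1 of nontumor NK-like cells turned to 0.03 and 0.02 and Gzma of tumor ILC1-like cells to -0.01. In tumor ILC1-like cells Prf1 turned to 0.02 with a class per cell, and Klra8 to 0.71 with a class per cell and 0.22 without list genes.

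Depth limits the nontumor KO libraries most. At 1500 UMIs per cell, thinning left 302 of 394 NK-like and 224 of 242 ILC1-like cells of the nontumor KO library.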

Other observations

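The selections of Ig genes, of macrophage-like cells and of the interferon list over all classes were chosen only after the results were seen. Interferon-induced transcripts mark an antiviral response that most cell types can mount. The median log2 ratio of KO to HET of the list of interferon-induced genes was below 0 in 12 of 12 combinations of class and sort in tumor, from -0.54 to -0.03, and its counting interval lay below 0 in 8 of them. These combinations come from only 2 pairs of libraries in each tissue. The -0.54 is that of neutrophil-like cells of the NK1.1- sort, a different mix of clusters in KO and HET, and within their largest cluster the median was -0.10 (-0.34 to 0.03). In nontumor tissue it was below 0 in 9 of 11 combinations, from -0.32 to 0.27, with the interval below 0 in 5 and above 0 in 1. Its percentile among random lists was 1 or less in 8 combinations in tumor and in 2 in nontumor tissue. A small unnamed cluster led by Ifit3, Ifit1 and Cxcl10 held 1.56% of tumor NK1.1- cells in HET and 0.474% in KO, and 0.669% and 0.196% of the nontumor NK1.1- cells. In the NK1.1+ sort the differences were smaller, with 1.145% in HET and 0.600% in KO in tumor, and 0.787% and 0.456% in nontumor tissue.

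Macrophage-like cells of the tumor NK1.1+ sort (287 KO and 299 HET cells) differed in more genes than lymphocytes did, with 193 of 5741 higher in KO and 303 lower. TMM moved all ratios of this comparison by 0.17 and median-of-ratios factors by 0.19, so ratios near 0 have no settled direction. The acute-phase gene Saa3 was at 6.71 (4.79 to 12.61, on 1 UMI in HET), Cd209a, a marker of dendritic cells, at 4.98 (3.61 to 7.5, on 3 UMIs in HET), Cxcl9, a chemokine induced by interferon gamma, at 3.02, the IL-1 antagonist Il1rn at 2.78 and Clec4e at 2.17. Clec4f, a marker of Kupffer cells, was at -3.28 and Lilra5 at -1.78. The inflammatory myeloid list had a median of 1.18 (1.1 to 1.25), and Apoe, chosen after its values were seen, was at -0.31. In 1 cell lay 39.3% of the Cxcl9 UMIs of the KO cells. Macrophage-like cells of the nontumor sort (343 KO and 109 HET cells) went the other way, in these genes, with Cxcl9 at -6.43 (-12.32 to -4.51, on 1 UMI in KO), Il1rn at -3.97, Clec4e at -2.37 and Lilra5 at 1.21. By size 26 genes were higher in tumor KO but lower in nontumor KO and 8 the reverse, while 5 were higher in both tissues (Ngp, S100a8, S100a9, H2-M2 and Ifitm6) and 1, Klra3, was lower in both. Ngp, S100a8 and S100a9 are neutrophil genes and Klra3 is an NK receptor gene, so free RNA from other cells is not excluded for them. Of the nontumor macrophage-like cells, 308 in KO and 27 in HET came from a cluster of few UMIs (medians 908.5 and 1699.0), so the tissues compare unlike mixes.

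Immunoglobulin constant regions differed between the libraries in plasma-like cells. In the tumor NK1.1- sort, Igha had 78802 UMIs in 79 HET cells and 50294 UMIs in 48 KO cells, while Ighg2b had 4270 and 45905 UMIs, Ighg2c 12 and 39266 UMIs, and Ighg1 0 and 10002 UMIs. In the nontumor NK1.1- sort Ighg2c went the other way, with 18947 UMIs in 31 HET cells and 1161 UMIs in 338 KO cells. There Ighg1 had 8615 and 5087 UMIs, while Ighg2b had 3230 and 18616 UMIs. Over all cells of the tumor NK1.1+ libraries Ighg2b was 4.40 CPM in HET and 912 CPM in KO. With 1 library per group a few plasma cell clones are enough to set such levels.

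The labels give an ending of the cell barcodes for each library in the aggregated matrix of all 8 libraries. For 3 libraries the cells with that ending carried the barcodes of the library's own matrix, and for 5 they carried those of another library. That matrix was left out for this reason. Klrb1c stood at 106 to 371 CPM in the libraries labelled NK1.1+ and at 3.21 to 9.08 CPM in those labelled NK1.1-, as their own labels of the sort require. By the endings, the libraries with 371 and 233 CPM would be NK1.1- and those with 5.66 and 9.08 CPM NK1.1+. These values argue against libraries mislabelled by sort. Whether the endings or the libraries are mislabelled by tissue or genotype was not settled. Il27ra over all cells was lower in the library labelled KO in each of the 4 pairs of tissue and sort, with separate intervals. That level also follows the mix of classes. Within the nontumor NK1.1+ pair the log2 ratio was 0.21 in NK-like, -0.49 in ILC1-like and -0.16 in innate-like T-like cells. Gm42031 was lower in 14 of 14 class comparisons, but it was singled out after its values were seen. So these values do not settle whether the 2 genotypes were exchanged within some pairs. An exchange in all pairs was not checked, nor were the labels of tissue.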
